A study of Caenorhabditis elegans with 3 samples.

How the data were processed

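Chromatin immunoprecipitation followed by sequencing was carried out on whole mixed-stage embryos of Caenorhabditis elegans that carry a transgene expressing BED-3, a BED-type zinc finger protein, fused to GFP and FLAG tags. The precipitation used an antibody against GFP. Per the labels, embryos were collected by bleaching, their age is given as 4 hours, chromatin was sonicated, and the size range was 200 to 800 bp. The series holds 1 group with 3 biological replicates, numbered 1, 3 and 4. No control group was analysed here, so no contrast between groups was made.

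The 5 peak lists are the authors' own, in ce11 coordinates per the labels. The aligner and the peak caller are not given in the sources used here. Per the deposited file listing, each replicate has a list called from its own alignments, and a pooled list was called from the alignments of replicates 1, 3 and 4 together. All of these lists used the same control alignment, which was not analysed here. The optimal list was derived from the relaxed lists of replicates 3 and 4 and the pooled list by the irreproducible discovery rate, per the deposited file listing. The signal of a peak is the deposited value of the authors' caller and was used to rank or filter peaks within a list. The deposited −log10 q of every optimal peak was 2.49, the highest value in the pooled list, and that column was not used to rank peaks. Start, end and summit offset are the deposited coordinates of each peak, and positions are given here counted from 1. Read depth per sample was not analysed here, so precision is given by the number of peaks and replicates.

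All 589 optimal peaks were present in the pooled list, and 589 pooled peaks reached the lowest optimal signal of 122. The optimal list is therefore the top of the pooled list by signal. Because replicates contribute reads to the pooled list, the optimal peaks are not independent of the replicates. The background was the 29411 pooled peaks with no optimal summit within 100 bp, called the remaining relaxed peaks.

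Gene models were those of Ensembl release 115 on WBcel235, which is the ce11 assembly, and every peak ended within the length of its chromosome in that reference. Genes without an Ensembl name, or sharing one, took the RefSeq symbol of the same identifier, and mitochondrial genes the RefSeq feature at the same place. A peak was assigned to the gene with the nearest annotated 5′ end within 2000 bp of its summit. The promoter window ran from 1000 bp upstream to 200 bp downstream of a 5′ end. Small RNA genes were nuclear genes annotated as tRNA, snoRNA, snRNA or rRNA, and a peak counted as lying at one when its summit was within 200 bp of the gene. Mitochondrial genes and genes annotated as other non-coding RNA, such as rpr-1 and mrpr-1, did not count. Settings without peaks at small RNA genes therefore keep the mitochondrial peaks.

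A peak counted as found in a replicate when a summit lay within 100 bp among the 1000 highest-signal peaks of that replicate's own list. Chance was taken from 1000 random placements of the optimal peaks on the same chromosomes. Signal agreement between replicates was tested across peaks, which are not independent replicates, with 100000 permutations. Shares were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment within each family: 7 chromosomes, 30 gene lists, 2080 canonical 6-mers and 9 preset motifs. For gene lists the background was the 13824 genes assigned any pooled peak. Sequence windows of 101 bp around summits were compared with remaining relaxed peaks matched 5 to 1 on GC content. Confidence intervals at 95% for shares of peaks are exact Clopper-Pearson intervals and cover counting error only. The threshold was an adjusted p of 0.05.

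Apart from tests marked below as outside this plan or added later, the tests, gene lists, motifs and most alternatives were fixed before the data were examined. So was the rule for named genes: those assigned the 25 highest optimal peaks, 4 members of each list that passed, up to 2 of each other list, and bed-3, blmp-1, unc-119, lin-39, nhr-25, nhr-23 and lin-29. The alternatives fixed then varied matching distance, list depth, windows, assignment, backgrounds and GC matching, and left out each replicate in turn. Leaving out a replicate kept the optimal peaks found in the others. Its reads stayed in the pooled list and the background list was unchanged, so this is a stricter filter of peaks. As the deposited lists give no irreproducible discovery rate per peak, the stricter threshold was the upper part of the optimal list by signal, 294 peaks. Alternatives restricted to nuclear peaks, to coding genes, to peaks away from small RNA genes, to a GC-matched background for chromosome X, or to each replicate's own 589 highest peaks were added after seeing the data.

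The procedures were tested on simulated data. Of 50 6-mers planted in 10% of 589 background windows, 49 were recovered, and 0 of 10400 passed with none planted. In each of 20 draws, 30% of the members of a gene list were planted among 13824 genes, and all 20 plantings were recovered. Only lists with at least 20 background members were planted, so recovery of smaller lists was not tested. With none planted, 0 of 600 passed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.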

Results

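Chromatin precipitated with GFP-tagged BED-3, a zinc finger protein that acts in vulval and epidermal cell divisions and in moulting, was profiled in embryos. The series held 3 biological replicates of 1 group. No untagged precipitation was analysed here, so called peaks are not shown to be sites of BED-3 binding. The replicate lists held 26338 peaks (replicate 1), 29455 peaks (replicate 3) and 30000 peaks (replicate 4). The pooled list held 30000 peaks, and the optimal list held 589, with a median width of 456 bp. Of these, 570 lay on nuclear chromosomes and 19 on the mitochondrial genome, and 8 intervals were repeats of another interval with a different summit.

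The strongest optimal peaks lay on mitochondrial DNA and at snoRNA genes. Among the 25 highest peaks, 13 were mitochondrial, assigned to ND5, ND4, ND1, ND2, COX1, CYTB, both ribosomal RNA genes and the tRNA genes for cysteine, leucine and lysine. The highest, with a signal of 2000 in the authors' unit, had its summit at position 12456 within the coding exon of ND5, a subunit of respiratory complex I. The strongest nuclear peak (V, 12303395 to 12303905, signal 1360) lay over the snoRNA gene C51F7.4, whose 5′ end was 37 bp from the summit. Peaks at the snoRNA genes W03C9.9 (signal 1288), ZK265.10 (1052), T03F7.8 (992), T06C12.16 (991), ZK994.7 (921), T02E1.9 (755) and C10C6.8 (724) followed. The other nuclear members of this set were the coding genes K12H4.5 (III, 8043748 to 8044201, signal 1128) and atx-2 (III, 10461134 to 10461489, signal 732), the leucine tRNA gene C04A11.t1 (X, 13665375 to 13665815, signal 828) and the non-coding gene F52D10.7 (signal 761). The nuclear peaks of this set were among the 1000 highest in every replicate. The mitochondrial peaks at the small ribosomal RNA gene, ND4, ND2, tRNA-Lys and both at COX1 were not, and those at ND4 and 1 of the COX1 sites had a match in replicate 1 alone.

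The first comparison asked whether called peaks recurred between replicates. Peaks at C51F7.4 ranked 6 in replicate 1, 6 in replicate 3 and 7 in replicate 4, and those at atx-2, the worm ataxin-2 gene, ranked 29, 30 and 21. The peak at lit-1, a kinase gene of the Wnt pathway, ranked 262 in replicate 4 but 17523 in replicate 1 and 14921 in replicate 3. Of the 589 optimal peaks, 335 were found in every replicate (56.9%, 95% interval 52.8 to 60.9), against a mean of 2.47 and a highest value of 8 over random placements (permutation p = 0.001, the smallest they can give, one-sided). With summits matched within 50 bp, 215 were. The optimal peaks are the top of a list pooled from these replicates' reads, so a count above random placement was largely set in advance. The permutation p is therefore no measure of independent recurrence. Replicate 1 held 471 of the 589 optimal peaks among its 1000 highest peaks, replicate 3 held 421 and replicate 4 held 550. Of the 19 mitochondrial peaks, 10 were found in every replicate, and of the 570 nuclear peaks, 325.

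Signal at the optimal peaks rose together in each pair of replicates. Spearman's rho was 0.697 for replicates 1 and 3 over 500 matched peaks, 0.732 for replicates 1 and 4 over 536, and 0.721 for replicates 3 and 4 over 521. Pearson's r of log2 signal was 0.74, 0.77 and 0.76. Each of the 6 coefficients had a permutation p and an adjusted p of 1e-05, the smallest the permutations can give. Replicates shared a control alignment, so part of this agreement can come from it. Independent of the pooled list, replicates 1 and 3 shared 370 of their 1000 highest peaks, replicates 1 and 4 shared 461, and replicates 3 and 4 shared 418, against 10.8, 8.47 and 7.86 at random.

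**Figure D1:**
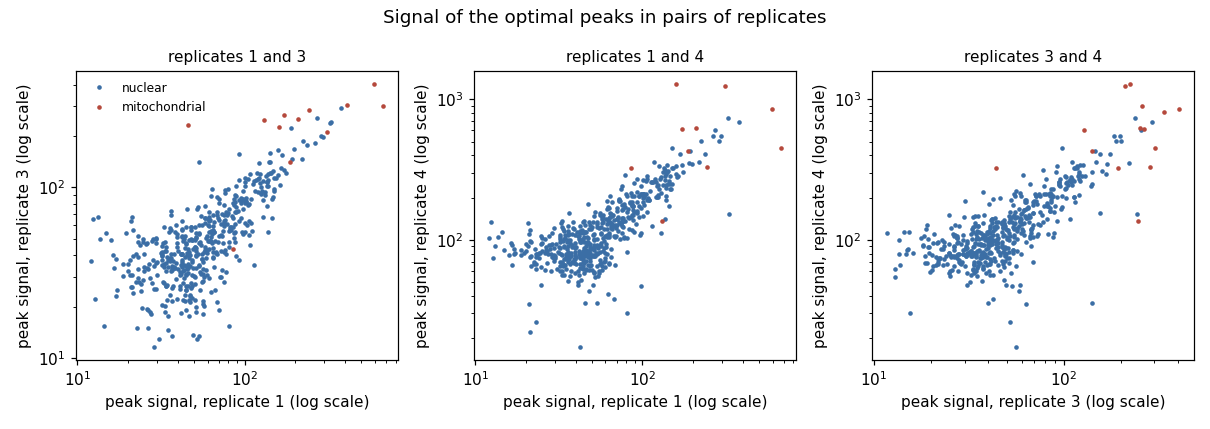
Signal of the optimal peaks in each pair of replicates, both axes in the authors' signal unit on a log scale; each point is 1 optimal peak with a match within 100 bp, blue for nuclear and red for mitochondrial. Signals rise together, with rho between 0.697 and 0.732, and mitochondrial points lie mostly at the upper end.

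The second comparison asked where optimal peaks lie relative to genes. Of the 589 optimal summits, 528 (89.6%, 95% interval 86.9 to 92.0) fell in a promoter window, against 42.9% of the remaining relaxed peaks (odds ratio 11.5, Fisher's exact p = 2.72e-123). The odds ratio was 17.6 without replicate 4 and, in settings added after seeing the data, 6.33 without peaks at small RNA genes and 6.05 in replicate 3's own list. Among the 549 nuclear optimal peaks within 2000 bp of a 5′ end the median distance was 57 bp, against 521 bp for 22897 remaining relaxed peaks within that distance. Farther away lay 21 nuclear optimal and 6514 remaining relaxed peaks. Exons and introns were compared as well, a test outside the plan fixed in advance. Exons of non-coding genes held 36.8% of optimal summits and 3.44% of the others, whereas introns held 13.4% and 40.3% and coding exons 4.75% and 14.4% (adjusted Fisher's exact p = 3.04e-148, 3.29e-45 and 1.45e-13). In the replicates' own lists, 85.2% ± 2.5 (SD, n = 3) of the 589 highest peaks and 42.9% ± 0.582 (SD, n = 3) of the rest lay in a promoter window.

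Summit position differed between gene classes, a comparison chosen after the data were seen. At the 165 peaks nearest to a nuclear tRNA gene, the median summit lay 15 bp inside the gene. The internal promoter of tRNA genes lies there, but so does sequence that many tRNA copies share, and the position cannot tell these apart. At the 50 peaks nearest to a snoRNA gene the median summit lay at -43 bp, upstream of the gene. Of these summits, 86% were upstream (permutation p = 1e-05 for tRNA against snoRNA, the smallest possible). At the 216 peaks nearest to a coding gene the median was -169 bp, with 89.4% upstream. At the 95 peaks nearest to a gene annotated as other non-coding RNA the median was 18 bp and the median pooled signal 182. A summit just inside the gene was thus not particular to tRNA genes. That class was not part of the tests of position and signal. Median pooled signal was 377 at snoRNA genes, 218 at tRNA genes and 165 at coding genes (permutation p = 1e-05 for each step, adjusted p = 1e-05). Repeated tRNA copies are not independent, so these permutation p-values, which all involve tRNA genes, are too small.

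**Figure D2:**
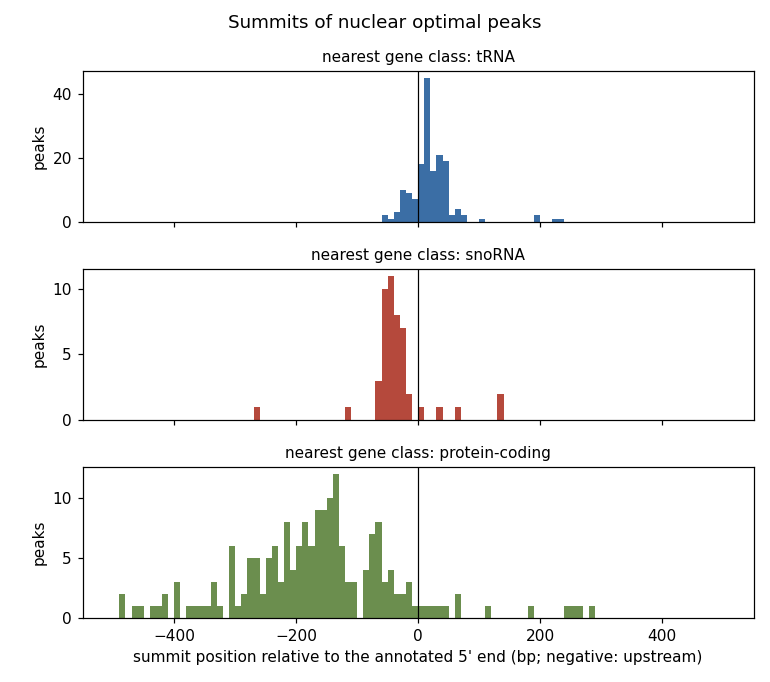
Position of nuclear optimal summits relative to the nearest annotated 5′ end in bp (x axis, negative upstream) and number of peaks (y axis), for peaks nearest to tRNA, snoRNA and protein-coding genes; positions beyond 500 bp are not drawn. Medians are 15, -43 and -169 bp.

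The third comparison asked whether optimal peaks favour chromosome X. Chromosome X held 132 of the 589 optimal peaks (22.4%, 95% interval 19.1 to 26) and 14.5% of the remaining relaxed peaks (odds ratio 1.70, adjusted Fisher's exact p = 1.70e-06). Chromosomes IV (odds ratio 0.676, adjusted Fisher's exact p = 0.00507) and V (odds ratio 0.715, adjusted Fisher's exact p = 0.0112) held fewer, and the mitochondrial genome held 3.23% against 0.0034% (adjusted Fisher's exact p = 3.80e-31). Chromosomes I, II and III did not pass. In the replicates' own lists, X held 22.7% ± 0.196 (SD, n = 3) of the 589 highest peaks and 15.8% ± 1.73 (SD, n = 3) of the rest. Nuclear tRNA genes are themselves frequent on X, which holds 276 of 612 (45.1%). Without peaks at small RNA genes, a setting added after seeing the data, X held 13.0% of 331 optimal peaks and 14.3% of the others (odds ratio 0.897, Fisher's exact p = 0.580).

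**Figure D3:**
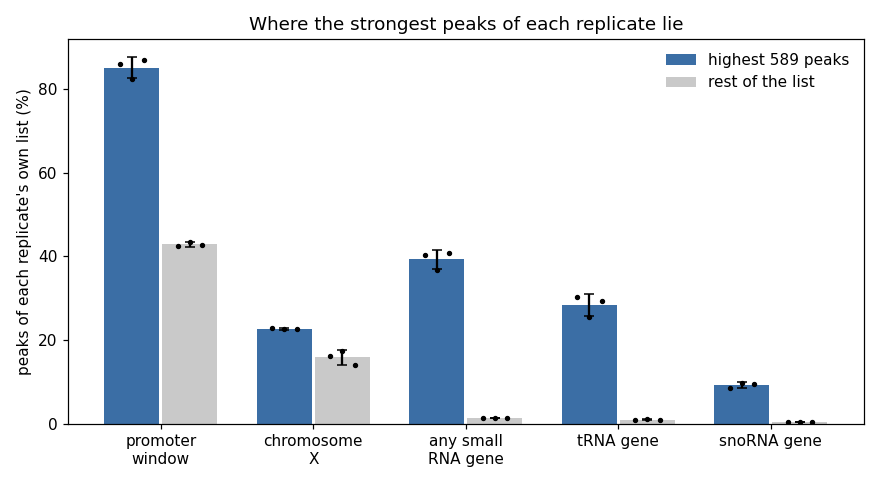
Share of peaks in percent (y axis) that lie in a promoter window, on chromosome X, or within 200 bp of small RNA, tRNA or snoRNA genes (x axis), for the 589 highest peaks of each replicate's own list and the rest of that list; bars are means, error bars SD and points the 3 replicates. For any small RNA gene the means are 39.3% and 1.34%.

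The fourth comparison asked which gene groups hold optimal peaks. Of 30 lists, tRNA, snoRNA and snRNA genes passed, all with more peaks than other genes, and 4 lists had an unadjusted p under the threshold. An optimal peak was assigned to 165 of 356 tRNA genes (46.3%, against 2.84% of other genes, odds ratio 29.5, adjusted Fisher's exact p = 4.22e-139). The sequence of 472 of 612 nuclear tRNA genes is repeated. Such copies are not independent, so p-values that count each tRNA gene separately are too small. The members with the highest signal were the mitochondrial genes for tRNA-Cys (1816), tRNA-Leu (1444) and tRNA-Lys (765) and the nuclear gene C04A11.t1 (828). Among snoRNA genes, which guide RNA modification, 49 of 191 held one (25.7% against 3.66%, odds ratio 9.08, adjusted Fisher's exact p = 2.38e-25), led by C51F7.4, W03C9.9, ZK265.10 and T03F7.8.

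Further measures of tRNA and snoRNA genes were added after the data were seen. In the replicates' own lists, 28.4% ± 2.60 (SD, n = 3) of the 589 highest peaks lay within 200 bp of a tRNA gene and 9.22% ± 0.643 (SD, n = 3) within that distance of a snoRNA gene. Many tRNA genes share their sequence with other copies. None of the 25 nuclear tRNA genes whose every 36-mer occurs once in the genome had an optimal peak within 200 bp, against 201 of the other 587 (Fisher's exact p = 4.51e-05). Of the 304 snoRNA genes with only unique 36-mers, 49 had one (16.1%, against 1.40% of other nuclear genes, odds ratio 13.5, Fisher's exact p = 2.61e-35). Read length and the handling of reads with several matches are not given in the sources used here.

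Among snRNA genes, whose RNAs act in splicing, 7 of 39 held an optimal peak (17.9% against 3.92%, odds ratio 5.36, adjusted Fisher's exact p = 0.00754). The leading members were W05B2.8 (signal 508), sup-6 (239), WBGene00195000 (233) and sls-2.1 (209), an SL2 spliced leader gene. Of these, W05B2.8, WBGene00195000 and sls-2.1 had no summit within 100 bp in the list of replicate 3. The snRNA result was lost when peaks were required in the other replicates without replicate 1 (odds ratio 3.00, adjusted Fisher's exact p = 0.559) and without replicate 4 (odds ratio 1.05, adjusted Fisher's exact p = 1). It was kept without replicate 3 (odds ratio 4.75, adjusted Fisher's exact p = 0.0462). In the replicates' own lists, a setting added after seeing the data, it passed in replicates 1 (odds ratio 6.74) and 4 (7.42). It did not pass in replicate 3 (3.95, adjusted Fisher's exact p = 0.124).

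The other 27 lists did not pass. Ribosomal protein genes came nearest, with 6 of 44 members (odds ratio 3.86, adjusted Fisher's exact p = 0.0555), led by rpl-3 (signal 434) and rpl-35 (326), and passed without replicate 3 (odds ratio 5.11, adjusted Fisher's exact p = 0.0199) but not without replicate 1 (3.60, 0.311) or replicate 4 (4.03, 0.221). In the replicates' own lists they did not pass (adjusted Fisher's exact p = 0.180, 0.350 and 0.152 in replicates 1, 3 and 4). Members of other lists with an optimal peak were lin-35, the worm retinoblastoma gene (331), daf-19 (209), a ciliary regulator, nhr-47 (197), fbxb-85 (188), him-17 (177), lit-1 (146), hsp-3 (144), tba-2 (136), the histone genes his-68 (370) and his-72 (129), and the microRNA genes cel-mir-52 (375) and cel-mir-54 (188). In 16 lists no member held one by assignment to the nearest annotated gene. These were the collagens (0 of 88), Hedgehog-related, muscle, ceh homeobox, ztf zinc finger, GATA, Hox, Notch, T-box, bHLH, epidermal and seam, heterochronic, intestinal, moulting, pharyngeal and vulval genes. Apart from the collagens they had from 7 (GATA) to 40 (Hedgehog-related) background members, with 12 vulval, 13 epidermal and seam and 21 moulting genes. About 3.97% of other genes held a peak, so none among so few members does not show that peaks avoid these lists. By assignment to the nearest coding gene, a setting added after seeing the data, a peak was assigned to 4 of 100 collagens (col-85, col-181, col-94 and col-185), to the Hedgehog-related genes wrt-3 and grl-26, to ceh-2 of the ceh, vulval and pharyngeal lists, to epn-1 of the Notch list and to lin-14 of the heterochronic list. In that setting 0 of 26 lists passed by Fisher's exact test, and 1 had an unadjusted p under the threshold.

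By annotated class, protein-coding genes held an optimal peak less often than other genes in the background (217 of 8725, 2.49% against 6.49%, odds ratio 0.367, adjusted Fisher's exact p = 3.03e-29). So did piRNA genes (3 of 847) and pseudogenes (6 of 550), with adjusted Fisher's exact p of 2.33e-11 and 0.000171. The class of other non-coding RNA genes was lower as well (93 of 2882, odds ratio 0.769, adjusted Fisher's exact p = 0.0331). Of 4 rRNA genes, 2 held one, both mitochondrial (adjusted Fisher's exact p = 0.0140). The other genes in the comparisons that came out lower include the tRNA genes (165 of 356 with a peak) and snoRNA genes (49 of 191). Those lower values therefore partly restate the tRNA and snoRNA excess and do not by themselves show depletion. Counting coding 5′ ends only, a setting added after seeing the data, 421 of 9740 coding genes were assigned an optimal peak. Against all annotated genes the coding result no longer passed (odds ratio 0.882, adjusted Fisher's exact p = 0.258) and that of other non-coding RNA genes turned to an odds ratio of 1.03 (adjusted Fisher's exact p = 0.850).

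The fifth comparison asked which sequences mark the summits. The 6-mer GTTCGA, part of the B box of tRNA genes, was present within 50 bp of 21.7% of optimal summits and 5.67% of GC-matched relaxed summits (odds ratio 4.62, adjusted Fisher's exact p = 7.38e-27). CGAACC (18.7% against 4.41%), ACCACT (17% against 4.92%) and TAACCA (10.7% against 2.24%) followed, with adjusted Fisher's exact p of 2.81e-25, 4.48e-18 and 2.72e-15. On 1 strand or the other, GTTCGA and CGAACC overlap, as do ACCACT and TAACCA, so these are not separate findings. The sequence of 472 of 612 nuclear tRNA genes is repeated, so windows at such copies are not independent and these p-values are too small. In all, 217 of 2080 6-mers were more frequent and 147 less frequent. These counts were 550 and 318 without GC matching and 478 and 366 against windows 300 bp from the same summits. The count of less frequent 6-mers was 91 without replicate 4, 70 within 25 bp and 58 for the upper part of the list by signal. Without peaks at small RNA genes, a setting added after seeing the data, the odds ratio was 0.892 for GTTCGA, 0.739 for CGAACC, 1.28 for ACCACT (adjusted Fisher's exact p = 0.681) and 1.26 for TAACCA (adjusted Fisher's exact p = 0.767). None of these 4 was then more frequent past the threshold, and 89 6-mers were more frequent and 35 less frequent. Of 9 preset motifs, GCGCGC passed (59 peaks, against 4.89% of GC-matched peaks, odds ratio 2.17, adjusted Fisher's exact p = 5.45e-05), but not without replicate 4 (odds ratio 1.83, adjusted Fisher's exact p = 0.0581). The GATA, E-box, TATA, TCF, homeobox, GA-repeat, Sp1-like and BLMP-1-like motifs did not pass. Counting either direction, 8 of the 9 motifs passed without GC matching (GCGCGC odds ratio 6.41), 3 within 100 bp of summits, and 2 without replicate 3 or without peaks at small RNA genes. GC content was 48.9% ± 9.23 (SD over 589 windows) at optimal summits and 37.7% ± 9.78 at the remaining relaxed peaks.

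**Figure D4:**
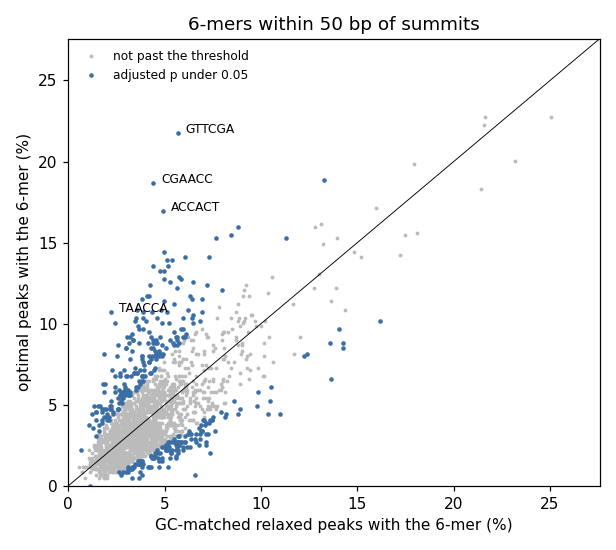
Percent of optimal peaks (y axis) and of GC-matched relaxed peaks (x axis) with each 6-mer within 50 bp of the summit; each point is 1 of 2080 6-mers, blue where the adjusted p is under 0.05, and the line marks equal shares. GTTCGA lies highest above the line, at 21.7% against 5.67%.

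The last comparison looked at the genes carried by the transgene and at preset regulators. The bed-3 gene (IV, 9916524 to 9921967) had no summit within 2000 bp in any of the 5 lists. The transgene carries further copies of bed-3, and how the control or any excluded regions affected calls at this locus is not given in the sources used here. Between its neighbours best-13 and trmt-10A lay 1 optimal peak (signal 124, rank 575), and the pooled list held 5 summits there against 7.46 at its mean density, with 3 against 6.55 in replicate 1, 1 against 7.33 in replicate 3 and 4 against 7.46 in replicate 4. Around unc-119, the transgene's marker, between com-1 and cut-6, no optimal peak was called, and the pooled list held 3 summits against 2.88 at its mean density. There, replicate 1 held 3 summits against 2.53, replicate 3 held 5 against 2.82 (best rank 800) and replicate 4 held 7 against 2.88. None of blmp-1, lin-39, nhr-25, nhr-23 and lin-29 had an optimal peak within 2000 bp. Their best pooled ranks were 977 for blmp-1, a transcription factor gene of moulting and developmental timing, 1972 for nhr-23, 4602 for nhr-25, 5176 for lin-29 and 8715 for lin-39, with 3629 for unc-119.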

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

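Settings restricted to nuclear peaks, coding genes, peaks away from small RNA genes, a GC-matched background for X or each replicate's own list were chosen only after the results were seen. Of 188 alternative values, 155 kept their direction and side of the threshold, or for counts stayed within 1.5 times. Those for signal agreement were among these, as were the odds ratios for promoters (6.05 to 17.6), tRNA genes (16 to 42.2) and snoRNA genes (6.22 to 16.9). Without peaks at small RNA genes, the odds ratio turned to 0.897 for X, 0.892 for GTTCGA and 0.739 for CGAACC, ACCACT (1.28) and TAACCA (1.26) no longer passed, and 89 6-mers were more and 35 less frequent. Against all annotated genes it was 0.882 for coding genes and 1.03 for other non-coding RNA genes. The upper part by signal held 294 peaks, gave 5.57 for snRNA genes, no longer passing, and left 58 less frequent 6-mers. At 50 bp, 215 peaks were found in every replicate. Leaving out replicates gave 1.05 to 4.75 for snRNA genes and replicate 3's own list 3.95. Ribosomal protein genes passed by promoter assignment (3.20), against all genes (7.02) and with nuclear peaks (3.97), and gave 3.60 to 5.11 without single replicates. With coding genes alone, 0 lists passed by Fisher's exact test, and 1 had an unadjusted p under the threshold. More frequent 6-mers numbered 550 without GC matching and 478 against windows 300 bp away, and less frequent ones 318 and 366, 70 at 25 bp and 91 to 135 without single replicates. Of the preset motifs, 3 passed at 100 bp, 8 without GC matching, 2 away from small RNA genes and 0 to 2 without single replicates, where GCGCGC gave 1.83 to 2.17. The cause of these changes was not tested, except that fewer peaks enter some settings. Groups share no replicate numbers, as there is 1 group. Read depth was not analysed here.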

Other observations

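The tests of tRNA and snoRNA genes by unique 36-mers or 24-mers, of ribosomal protein genes and of mitochondrial coverage were chosen only after the results were seen, as were the product words, the genes named here and the 6-mers away from small RNA genes. Outside the preset lists, 2 optimal peaks were assigned to rpr-1, the RNA of RNase P, the higher at I, 13463777 to 13464140 (signal 642). A peak also lay at mrpr-1, the RNA of RNase MRP (II, 7200073 to 7200388, signal 394). The higher peak at rpr-1 ranked 27, 40 and 26 in replicates 1, 3 and 4, and that at mrpr-1 ranked 96, 109 and 88. Whether genes of this kind hold peaks more often than others was not tested.

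Away from small RNA genes, 195 coding genes had an optimal peak within 500 bp of a 5′ end. Of 106 words in their product names, 3 passed: subunit (34 of 388 genes, odds ratio 3.26, adjusted Fisher's exact p = 6.71e-06), complex (14 of 127, 3.91, 0.00288) and mitochondrial (14 of 136, 3.62, 0.00408). Among the genes whose product is described as mitochondrial were tomm-20, nuo-2 and idhg-1. The words share genes, such as apb-1 and cogc-2 for subunit and complex, and tomm-20 and idhg-1 for subunit and mitochondrial. They are therefore not separate findings. At the 331 peaks away from small RNA genes the leading 6-mers were CGCACA (18.7% against 5.20%, odds ratio 4.20), CGCGCA (19% against 5.44%) and TTGCAA (16% against 3.87%), each with an adjusted Fisher's exact p of 3.64e-11, and GCGCGC had an odds ratio of 3.73. The 331 include the 19 mitochondrial peaks, and genes annotated as other non-coding RNA did not count as small RNA genes.

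Of the 589 optimal peaks, 258 lay within 200 bp of a small RNA gene (43.8%, against 1.45% of remaining relaxed peaks). GC content as the whole cause is argued against, since the odds ratio was 23.4 against GC-matched peaks. Reads shared between copies are argued against for snoRNA genes unique in the genome, by every 36-mer (49 of 304, odds ratio 13.5 against other nuclear genes) or, with flanks of 200 bp, every 24-mer (42 of 216, 17); this holds for reads at least that long, as read length and the handling of reads with several matches are not given in the sources used here. For tRNA genes they stay open. Genes of unique tRNA sequence held a peak less often than repeated ones (odds ratio 0.387, Fisher's exact p = 3.64e-05), and of 25 whose every 36-mer is unique, 0 did (odds ratio 0), although 26 of all 140 unique ones did (odds ratio 16.1 against other nuclear genes, Fisher's exact p = 2.82e-21); the bounds set in advance overlapped and were both met, since an excess at unique genes does not exclude shared reads from near copies, and decayed genes among the unique ones could give the same result. Signal common to any precipitation at active loci may contribute and cannot be told apart, as ribosomal protein genes had an odds ratio of 3.74 among coding genes (adjusted Fisher's exact p = 0.0680) and no untagged precipitation was analysed here; no biological explanation was tested.

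The 19 mitochondrial peaks had a median signal of 944, against 187 for nuclear ones. They covered 54.6% of the mitochondrial genome, and 52.6% of them were found in every replicate against 57.0% of nuclear peaks (Fisher's exact p = 0.815). Both values met the bounds written for many copies of mitochondrial DNA per cell, but they cannot decide the question. Peaks of this number and width cover much of so short a genome whatever the cause, and 19 peaks are few. The control alignment used in calling them was not analysed here. No biological explanation was tested.

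The higher share of optimal peaks on X may follow from the place of tRNA genes. With peaks at small RNA genes removed the odds ratio for X was 0.897, whereas GC matching left it at 1.33 (Fisher's exact p = 0.0126), which argues against GC content as the whole cause. A tRNA gene on X held a peak about as often as an autosomal one (33.7% against 32.1%, Fisher's exact p = 0.729). No biological explanation was tested.

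Further hypotheses were left open. Whether a tRNA gene held a peak was not shown to depend on its amino acid type (permutation p = 0.897 over 21 types), and the bound set in advance for excluding it was wrong, since a p over the threshold does not show that the types are alike. The snoRNA genes inside a coding gene on the same strand held a peak in 12% of 183 cases and those outside in 19% of 163 (odds ratio 0.582, Fisher's exact p = 0.0749).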
